A study of Saccharomyces cerevisiae with 40 samples.

How the data were processed

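Budding yeast of strain Σ1278b grew on 20 nitrogen sources and on urea, with 3% glucose, in minimum medium for at least 10 generations, and was harvested in exponential growth at low density. Sources and urea were at 10 mM, tryptophan at 5 mM, and ammonium was given as ammonium sulfate. Each of the 40 arrays held polyA RNA of a source and of urea in the Cy5 and Cy3 channels, 2 arrays per source. In all, 18 sources had opposite dye orientations, and tryptophan and tyrosine had urea in Cy5 on both arrays.

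The values were deposited by the authors as centred log2 ratios of both channels, 1 per spot. That they are log ratios follows from their sign and range, and base 2 is an assumption, since no base is named in the sources used here. Normalization, scanner, background correction and filter are not given in the sources used here. Array medians lay within 0.01 of 0, so each array was centred as deposited. The direction Cy5 over Cy3 was taken from the labels, and opposite arrays correlated below 0 for all 18 sources. Arrays came in 2 tables, and whether these were normalized together is not given in the sources used here. Table, dye orientation and replicate number coincide for the 18 sources, so a dye bias of opposite sign in the 2 tables would shift every source alike and cannot be separated. Class and pair comparisons are free of such a shift.

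Each table has 12800 probes. Of these 10890 and 11188 named 1 gene, and 1910 and 1612 named none and were left out. Duplicate spots of a gene correlated at 0.885 to 0.982 (median 0.958) and were averaged. Spots without a value made up 15.3 to 39.4% of an array in the table with sources in Cy5 and 21.8 to 53.2% in the other. Of 5557 genes, 4332 with values on at least 30 of 40 arrays were tested, 1225 were not, and 1256 had values on all 40. A source was tested only with both arrays.

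The fit used limma 3.58.1 with statmod 1.5.0 in R 4.3.3, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Each gene had a signed term per source and a dye intercept over all 40 arrays, with 19 residual degrees of freedom for complete genes, and spread was moderated across genes (prior degrees of freedom 6.27, median residual SD 0.168). The ratio to urea was tested against 0, two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The dye term passed for 2042 genes. An F-test covered all sources. Across the 18 sources with both orientations, the difference between replicate 1 and replicate 2 of a source correlated over 0.1 with that of another source in all 153 pairs (median 0.440). A replicate block in place of the dye term was among the alternatives.

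The 7 amino acids that leave fusel alcohols were compared with the 13 others, the source being the unit, for genes with values on at least 4 and 7 sources. List means were compared between classes by exact permutation, two-sided. The 9 pairs of related molecules were compared as contrasts in the same fit, adjusted within each pair. The 20 fixed lists were tested per source with fry, two-sided, adjusted over lists and sources. Missing values were filled, for the spread only, with the fitted value plus a random residual of the gene, a step chosen after the data were seen.

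Named genes were the 12 highest and 12 lowest class differences, up to 4 highest and 4 lowest values per source with both arrays in the direction, the 20 largest F, up to 3 highest and 3 lowest differences per pair, genes of the direction check, and 2 to 4 members of a named list with the largest absolute value. Names were left out where space was short, and not always those of lowest rank. Comparisons, lists, pairs, classes and this rule were set before the data were examined.

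The fit was tested on simulated data with independent normal errors, 1 spread per gene for all sources and no urea error shared by arrays. The rates that follow hold for that setting only. Changes of 0.5 and 1 on the log2 scale were recovered in 69.1% and 97.8% of genes for leucine, 34.4% and 91.0% for leucine minus isoleucine and 90.4% and 96.7% for the class comparison, with 3, 4 and 6 unchanged genes called. The F-test recovered 15% and 75% of genes changed on leucine and tryptophan alone, with 4 unchanged genes called. Alternatives were no dye term, the replicate block, array medians subtracted, genes on all 40 or at least 20 arrays, the median of spots, array weights, only the arrays of the comparison, leaving out each array in turn, and for the class threonine in the fusel class, tryptophan and tyrosine left out, and arrays as the unit.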

Results

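Messenger RNA of budding yeast growing on 20 nitrogen sources was compared with RNA of cells growing on urea, with 2 arrays per source and 40 arrays in all. The question the series poses is how the choice of nitrogen source changes expression across the genome. An array gave values for 3294 to 5218 genes (median 4708), and the number of arrays limits the precision of what follows. Values are fitted log2 ratios of source over urea ± SE (n = 2 arrays per source), a negative value meaning less RNA than on urea. Each SE rests on a spread of the gene shared by all 40 arrays. It therefore does not show how far the 2 arrays of a source lay apart. Nothing in the labels says that the 2 arrays of a source came from separate cultures, so the p-values measure the spread between arrays, which can be technical. Urea RNA was the only control and sat on every array, and the labels do not say whether it came from a single culture. The 2 arrays of a source, each read as source over urea, correlated across genes at 0.370 (citrulline) to 0.801 (glutamine), genes not being independent replicates.

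Some genes moved the same way against urea on nearly every source. DUR3, the urea transporter gene, fell on all 20 sources (mean -2.52, SD 0.47 over sources), and DAL4, the allantoin permease gene, fell on 19, as did DAL7 and DAL2, which encode a malate synthase and allantoicase of allantoin use. SED1, which encodes an abundant cell wall protein, rose on all 20 sources (mean 2.17, SD 0.60). VEL1 rose on all 20 (mean 3.31, SD 0.81) and YOR387C on 19 (mean 3.98, SD 0.90), the highest fitted values on most sources. Both are genes of closely similar sequence whose probes were not tested for cross-hybridisation. The VEL1 call on glutamate ended without glutamate replicate 1 (2.17, adjusted p = 0.0611). The YOR387C calls ended without replicate 1 on leucine (2.32), glutamate (3.31), proline (3.17), serine (2.87), tryptophan (2.46) and tyrosine (2.55), and without replicate 2 on citrulline (3.25), with adjusted p values of 0.0555 to 0.146.

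Over all sources together, 2759 of 4332 genes departed from urea on at least 1 source by limma's moderated F-test. The largest F values were those of DAL4 (95.7, adjusted p = 2.4e-15), DAL7 (88.8), DAL5 (72.9), AAH1 (72.0), DAL2 (70.9), VBA1 (70.8), YHI9 (70.3), SDL1 (69.6), DUR3 (67.4) and GNP1 (66.1). AAH1 encodes adenine deaminase and fell on 16 sources, and VBA1, a vacuolar transporter gene of basic amino acids, also fell on 16. GNP1, a glutamine permease gene, rose on 14 and AGP1, a broad amino acid permease gene, on 17. The arginase gene CAR1 rose on 9 and fell on 4, and the GABA catabolism gene UGA2 rose on 5 and fell on 4. DAL80 (15 sources), ATG32 (13), FAA3 (13) and DSD1 (19) only fell among the sources where they passed, and SUL1, a sulfate permease gene, fell on 16 and rose on 1. Of the 4332 genes, 1120 passed on no source in the tests of single sources, 368 passed in both directions and 8 passed on all 20 sources.

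**Figure D1:**
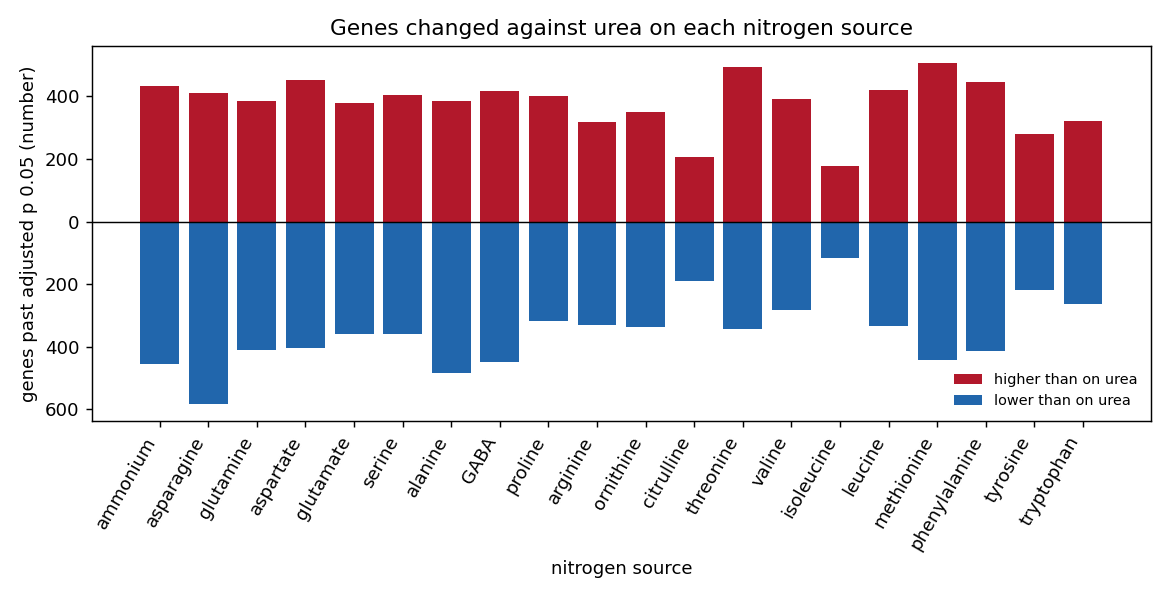
Number of genes higher and lower than on urea on each of the 20 nitrogen sources (adjusted p under 0.05, limma). The counts run from 295 genes on isoleucine to 995 on asparagine.

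Ammonium, asparagine and glutamine lowered genes for the transport and use of poorer nitrogen sources. On asparagine, DAL5, the allantoate permease gene, fell to -5.97 ± 0.37 (SE, n = 2 arrays), DAL80, a GATA repressor gene, to -5.45 ± 0.27, DAL4 to -4.81 ± 0.32 and DAL7 to -4.37 ± 0.27. On glutamine, DAL5 was at -5.41 ± 0.37, DAL7 at -4.54 ± 0.27 and the ammonium permease gene MEP2 at -3.85 ± 0.25, while BAP2, a branched-chain amino acid permease gene, rose by 2.99 ± 0.48 and the alcohol dehydrogenase gene ADH4 by 2.48 ± 0.36. On ammonium, DAL5 fell to -4.93 ± 0.37, DAL4 to -4.18 ± 0.32 and DAL7 to -3.84 ± 0.27, and SED1 rose by 2.41 ± 0.29. Of the nitrogen catabolite repression list (transporters and enzymes that good nitrogen sources repress), 1 of 26 rose and 24 fell (1 and 25 adjusted over the list alone, adjusted p = 3.1e-11) on asparagine, 1 of 24 rose and 19 fell (1 and 23 adjusted over the list alone, adjusted p = 1.9e-10) on glutamine and 1 of 26 rose and 22 fell (1 and 23 adjusted over the list alone, adjusted p = 1.3e-08) on ammonium. Across all genes on asparagine, 995 of 3953 tested genes changed, 412 higher and 583 lower (533 without replicate 1, 318 without replicate 2). On glutamine, 795 of 3188 tested genes changed, 385 higher and 410 lower (345 without replicate 1, 292 without replicate 2). With ammonium, 890 of 4261 tested genes changed, 434 higher and 456 lower (413 without replicate 1, 262 without replicate 2).

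On serine, aspartate, glutamate and alanine the allantoin and allantoate permease genes DAL4 and DAL5 fell as well. Serine lowered DAL5 to -4.99 ± 0.37 and DAL80 to -3.46 ± 0.27 (SE, n = 2 arrays), and raised CHA1, the catabolic serine and threonine deaminase gene, by 2.48 ± 0.32. Aspartate lowered DAL4 to -4.29 ± 0.32 and the malate synthase gene MLS1 to -3.11 ± 0.34, and raised BAP2 by 2.83 ± 0.48. Glutamate lowered DAL4 to -3.61 ± 0.32, CIT2, the peroxisomal citrate synthase gene, to -2.14 ± 0.21 and the pyruvate carboxylase gene PYC1 to -1.68 ± 0.18. Alanine lowered DAL5 to -3.58 ± 0.37 and VBA1 to -2.99 ± 0.26, and raised AGP1 by 2.86 ± 0.46. Of the catabolite repression list, 1 of 24 rose and 21 fell (1 and 21 adjusted over the list alone, adjusted p = 1.7e-09) on serine, 2 of 27 rose and 19 fell (2 and 20 adjusted over the list alone, adjusted p = 6.8e-07) on aspartate, 1 of 27 rose and 20 fell (2 and 21 adjusted over the list alone, adjusted p = 6.9e-07) on glutamate and 2 of 24 rose and 19 fell (2 and 20 adjusted over the list alone, adjusted p = 1.5e-07) on alanine. On serine, 766 of 3195 tested genes changed, 406 higher and 360 lower (321 without replicate 1, 296 without replicate 2). Under aspartate, 858 of 4022 tested genes changed, 453 higher and 405 lower (354 without replicate 1, 229 without replicate 2). For glutamate, 738 of 3627 tested genes changed, 380 higher and 358 lower (218 without replicate 1, 344 without replicate 2). In alanine cultures, 869 of 4013 tested genes changed, 384 higher and 485 lower (382 without replicate 1, 379 without replicate 2).

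GABA raised the genes of its own breakdown, and proline raised PUT2 of proline breakdown. On GABA, the permease gene UGA4 rose by 4.42 ± 0.18 (SE, n = 2 arrays), UGA2, the succinate semialdehyde dehydrogenase gene, by 3.85 ± 0.13, the GABA transaminase gene UGA1 by 3.56 ± 0.18 and GDH2, the NAD-dependent glutamate dehydrogenase gene, by 2.23 ± 0.22. LEE1, which encodes a zinc-finger protein, fell to -3.82 ± 0.43 and MLS1 to -3.48 ± 0.34. On proline, PUT2, a dehydrogenase gene, rose by 2.02 ± 0.15 and ADH4 by 2.35 ± 0.36, while PUT1, the proline oxidase gene, was at 1.14 ± 0.46 and did not pass (adjusted p = 0.0921). Proline lowered CIT2 to -2.81 ± 0.21 and DAL4 to -3.22 ± 0.32. Of the retrograde and citric acid cycle list, 7 of 17 fell (7 adjusted over the list alone, adjusted p = 0.000575) on proline, where PYC1 was at -1.90 ± 0.18 and DLD3, a lactate dehydrogenase gene of the retrograde response, at -1.41 ± 0.12. On GABA, 869 of 4108 tested genes changed, 419 higher and 450 lower (441 without replicate 1, 213 without replicate 2). On proline, 719 of 4176 tested genes changed, 401 higher and 318 lower (251 without replicate 1, 226 without replicate 2).

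Arginine, ornithine and citrulline raised CAR1, the arginase gene, to unequal extents. On citrulline CAR1 rose by 5.47 ± 0.23 (SE, n = 2 arrays) and CAR2, the ornithine transaminase gene, by 2.91 ± 0.17. CAR1 rose by 1.57 ± 0.23 on arginine and 1.72 ± 0.23 on ornithine. CAR2 rose by 0.86 ± 0.17 on arginine, a call that ended without arginine replicate 1 (0.49, adjusted p = 0.166), and was at 0.06 ± 0.17 on ornithine without passing, and at -0.26 without ornithine replicate 1. The ornithine values of CAR1 and CAR2 were chosen after they were seen. Citrulline also raised AGP1 by 6.16 ± 0.46 and lowered MLS1 to -3.00 ± 0.34, and ornithine raised the catalase gene CTT1 by 2.59 ± 0.44. Of the arginine biosynthesis list, 2 of 6 fell (3 adjusted over the list alone, adjusted p = 0.00319) on arginine, among them ARG3 (-0.87 ± 0.16), whose call ended without arginine replicate 1 (-0.21, adjusted p = 0.402). On arginine, 648 of 3702 tested genes changed, 318 higher and 330 lower (339 without replicate 1, 316 without replicate 2). On ornithine, 687 of 3339 tested genes changed, 350 higher and 337 lower (260 without replicate 1, 250 without replicate 2). On citrulline, 397 of 3922 tested genes changed, 206 higher and 191 lower (241 without replicate 1, 129 without replicate 2).

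The branched-chain amino acids leucine, isoleucine and valine raised AGP1, by 3.68 ± 0.46, 5.09 ± 0.46 and 3.56 ± 0.46 (SE, n = 2 arrays each), and lowered DUR3, to -2.69 ± 0.31, -2.36 ± 0.31 and -2.90 ± 0.31. Isoleucine also lowered HXT2, a glucose transporter gene, to -1.76 ± 0.18. Of the Gcn4 list (amino acid biosynthesis genes of the general control response), 20 of 27 rose (21 adjusted over the list alone, adjusted p = 3.3e-07) on leucine, led by ARG8 (1.59 ± 0.13) and LYS20 (1.40 ± 0.19) of arginine and lysine synthesis. On isoleucine, 6 of 26 rose (9 adjusted over the list alone, adjusted p = 0.0105) of that list. LEU4, a leucine synthesis gene, was at 0.92 ± 0.14 on isoleucine, and of the branched-chain synthesis list there 5 of 10 rose (5 adjusted over the list alone, adjusted p = 0.00918). On leucine, 755 of 4038 tested genes changed, 421 higher and 334 lower (248 without replicate 1, 287 without replicate 2). On isoleucine, 295 of 3108 tested genes changed, 178 higher and 117 lower (150 without replicate 1, 136 without replicate 2). On valine, 676 of 4136 tested genes changed, 392 higher and 284 lower (237 without replicate 1, 140 without replicate 2).

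Methionine and threonine raised amino acid permease and biosynthesis genes together. On methionine BAP2 rose by 3.53 ± 0.48 (SE, n = 2 arrays), GNP1 by 2.86 ± 0.21 and ARO10, a decarboxylase gene of the Ehrlich pathway, by 3.32 ± 0.39. The sulfate assimilation genes MET3 and MET14 fell to -2.60 ± 0.15 and -2.49 ± 0.16, and of the sulfur amino acid list 3 of 17 rose and 13 fell (3 and 13 adjusted over the list alone, adjusted p = 2.9e-10). Of the Gcn4 list, 22 of 26 rose (25 adjusted over the list alone, adjusted p = 2.0e-08) on methionine and 14 of 27 rose (16 adjusted over the list alone, adjusted p = 5.2e-05) on threonine. Of the branched-chain synthesis list 9 of 10 rose (9 adjusted over the list alone, adjusted p = 4.6e-08) on methionine, led by BAT1 (1.77 ± 0.17), a transaminase gene. Threonine raised AGP1 by 4.72 ± 0.46, GNP1 by 2.96 ± 0.21 and CHA1 by 2.71 ± 0.32, and lowered HXT2 to -2.00 ± 0.18. On methionine, 949 of 3983 tested genes changed, 507 higher and 442 lower (499 without replicate 1, 366 without replicate 2). On threonine, 837 of 3897 tested genes changed, 494 higher and 343 lower (355 without replicate 1, 229 without replicate 2).

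The aromatic amino acids raised ARO10, which encodes the phenylpyruvate decarboxylase, by 7.46 ± 0.40 on tyrosine, 6.58 ± 0.40 on tryptophan (5 mM, against 10 mM for the other sources) and 4.01 ± 0.39 on phenylalanine (SE, n = 2 arrays each). Single arrays of ARO10 read 5.92 and 8.92 on tyrosine and 6.61 and 6.46 on tryptophan, a difference in spread that the shared SE does not show. AGP1 rose by 6.50 ± 0.48 on tryptophan, 5.78 ± 0.48 on tyrosine and 4.24 ± 0.46 on phenylalanine. TAT2, the tryptophan and tyrosine permease gene, rose by 4.04 ± 0.53 on tyrosine. SED1 rose by 3.43 ± 0.30 and DUR3 fell to -3.92 ± 0.32 on tryptophan, and INO1, the inositol phosphate synthase gene, fell to -2.03 ± 0.29 on tyrosine. Of the Ehrlich pathway and Aro80 list, 3 of 5 rose (3 adjusted over the list alone, adjusted p = 2.2e-08) on tryptophan and 2 of 4 rose (2 adjusted over the list alone, adjusted p = 9.3e-06) on tyrosine. On phenylalanine 2 of 7 rose and 1 fell (2 and 1 adjusted over the list alone, adjusted p = 0.0157), the fall being that of ARO8 (-0.98 ± 0.15), an aromatic transaminase gene. On tyrosine and tryptophan both arrays carried urea in Cy5, so there the dye term rests on the other sources. On phenylalanine, 860 of 4213 tested genes changed, 447 higher and 413 lower (181 without replicate 1, 305 without replicate 2). On tyrosine, 500 of 3323 tested genes changed, 280 higher and 220 lower (361 without replicate 1, 240 without replicate 2). On tryptophan, 585 of 3118 tested genes changed, 322 higher and 263 lower (528 without replicate 1, 268 without replicate 2).

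**Figure D2:**
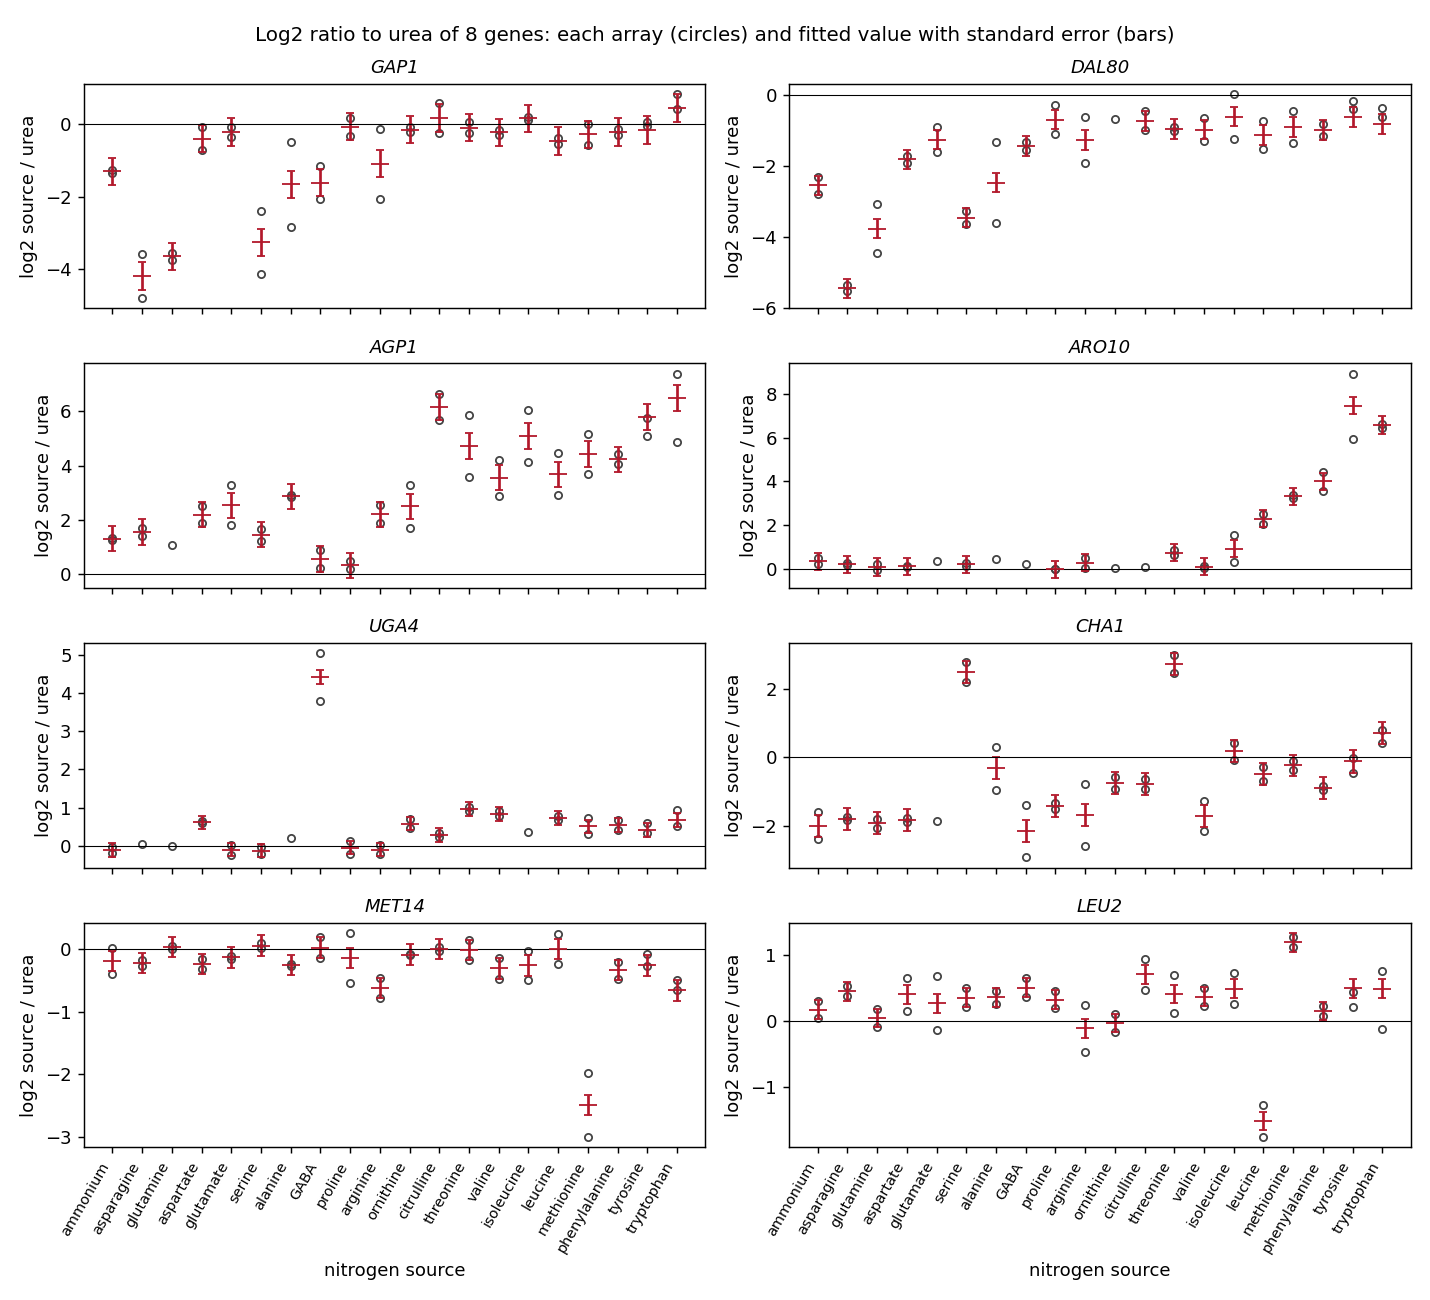
Log2 ratio of source over urea for selected genes on each of the 20 nitrogen sources, with circles for single arrays and bars for the fitted value ± SE. Sources with a single array value have a circle and no bar. The fitted value of ARO10 is highest on tyrosine at 7.46, where the arrays read 5.92 and 8.92.

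Lists of related genes were tested for a shift in a single direction on each source, with fry over 20 lists and 20 sources, and 158 of the 400 tests passed. The test asks whether the genes of a list move one way on balance and does not compare them with other genes. Median, mean and test differed in sign in 43 of the 400 tests and in 0 of the 158 that passed. The nitrogen catabolite repression list fell on 14 sources (medians -2.17 to -0.33). It holds DUR3, which fell on all 20 sources, and DAL2, DAL4 and DAL7, which fell on 19. A fall of the list against urea thus does not by itself show repression by the source. GAP1 of this list was at -4.19 on asparagine but at -0.22 on valine and -0.21 on phenylalanine. DAL4 was at -4.81, -2.67 and -3.32 on these sources. The fewest members fell on valine, where 4 of 26 rose and 9 fell (4 and 13 adjusted over the list alone, adjusted p = 0.0132), and the most on asparagine. It did not pass on citrulline, isoleucine, methionine, threonine, tryptophan and tyrosine. The SPS sensor list, amino acid permease genes under the control of an external amino acid sensor, rose on 17 sources (medians 0.74 to 2.50). It did not pass on glutamate, glutamine and proline. This does not mean that no permease gene rose there, since BAP2 was at 2.76 on glutamate and 2.99 on glutamine. The highest median over the 20 sources, 2.54, lay outside the 17 that passed. Few members had values there, with 2 tested for glutamine minus glutamate. On methionine 6 of 7 rose (6 adjusted over the list alone, adjusted p = 7.8e-10), on threonine 6 of 7 rose (6 adjusted over the list alone, adjusted p = 1.3e-08) and on tryptophan 6 of 7 rose (6 adjusted over the list alone, adjusted p = 1.3e-08). DIP5, a dicarboxylic amino acid permease gene of this list, fell on some of these sources, to -2.06 ± 0.40 on asparagine. The unfolded protein response list, of chaperone and redox genes of the endoplasmic reticulum, rose on 18 sources (medians 0.18 to 1.16), all but tryptophan and tyrosine, the methionine call ending with a replicate block in place of the dye term (adjusted p = 0.0639). On aspartate 11 of 11 rose (11 adjusted over the list alone, adjusted p = 6.7e-08), with the chaperone gene KAR2 at 1.50 ± 0.20 and the oxidase gene ERO1 at 1.46 ± 0.21. Its members HAC1 (19 sources), FPR2 (16) and ERO1, LHS1 and SIL1 (15 each) rose on most sources. So did AGP1 (17) and BAP2 (16) of the SPS list. A rise of either list against urea thus does not by itself show induction by the source. Leaving out an own array ended the catabolite repression call with GABA replicate 1 (0.0889), GABA replicate 2 (0.407), leucine replicate 2 (0.0510), phenylalanine replicate 2 (0.108), proline replicate 1 (0.0642), proline replicate 2 (0.101) and valine replicate 2 (0.139), the SPS call with GABA replicate 2 (0.0920) and ornithine replicate 1 (0.0631) and the unfolded protein response call with citrulline replicate 1 (0.0862), citrulline replicate 2 (0.242), leucine replicate 1 (0.155), methionine replicate 1 (0.463), methionine replicate 2 (0.0572) and threonine replicate 1 (0.0799), the adjusted p then reached being in parentheses.

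Among amino acid lists, Gcn4 targets rose on 6 sources, namely isoleucine, leucine, methionine, threonine, tryptophan and tyrosine. On tyrosine 15 of 27 rose (17 adjusted over the list alone, adjusted p = 0.000186) and on tryptophan 12 of 24 rose (16 adjusted over the list alone, adjusted p = 0.000326). Arginine biosynthesis genes, several of which are Gcn4 targets, rose on 7 sources (isoleucine, leucine, methionine, threonine, tryptophan, tyrosine and valine) and fell on arginine and glutamate. On leucine 6 of 7 rose (6 adjusted over the list alone, adjusted p = 1.5e-07) and on methionine 6 of 7 rose (7 adjusted over the list alone, adjusted p = 3.9e-08). Lysine biosynthesis genes rose on GABA, alanine, isoleucine, leucine, methionine and threonine and fell on phenylalanine. Of the lysine genes 4 of 7 rose (4 adjusted over the list alone, adjusted p = 1.1e-06) on methionine. The branched-chain synthesis list rose on isoleucine, methionine, threonine, tryptophan and tyrosine, the tryptophan call ending with the replicate block (adjusted p = 0.107). On threonine 6 of 10 rose (7 adjusted over the list alone, adjusted p = 0.000752). Sulfur amino acid genes fell on ammonium, arginine, glutamate, methionine and phenylalanine and rose on leucine and threonine, the phenylalanine call ending with the block (adjusted p = 0.0508). On threonine 8 of 19 rose (9 adjusted over the list alone, adjusted p = 0.00128), with the methionine permease gene MUP1 at 2.24 ± 0.22. The Ehrlich list rose on 7 sources (isoleucine, leucine, methionine, phenylalanine, threonine, tryptophan and tyrosine) and fell on glutamine through ARO8 (-1.56 ± 0.15). One-carbon and purine genes rose on asparagine, citrulline, isoleucine, leucine, methionine, threonine, tryptophan and tyrosine. On methionine 8 of 12 rose (9 adjusted over the list alone, adjusted p = 1.6e-05). Calls that ended when an own array was left out follow, with the adjusted p then reached. For Gcn4 this held for isoleucine replicate 1 (0.485). For arginine genes it held for arginine replicate 1 (0.726), glutamate replicate 1 (0.150), glutamate replicate 2 (0.0955), isoleucine replicate 1 (0.129), valine replicate 1 (0.179) and valine replicate 2 (0.135). For lysine genes it held for GABA replicate 1 (0.221), GABA replicate 2 (0.0980), alanine replicate 2 (0.627), isoleucine replicate 1 (0.604), phenylalanine replicate 1 (0.212) and phenylalanine replicate 2 (0.0569). For branched-chain synthesis it held for isoleucine replicate 1 (0.290), tryptophan replicate 1 (0.153) and tyrosine replicate 2 (0.165). For sulfur genes it held for ammonium replicate 1 (0.386), arginine replicate 1 (0.213), arginine replicate 2 (0.0629), glutamate replicate 2 (0.197), leucine replicate 1 (0.149), leucine replicate 2 (0.102), phenylalanine replicate 1 (0.140) and phenylalanine replicate 2 (0.304). For the Ehrlich list it held for glutamine replicate 1 (0.0752), glutamine replicate 2 (0.448), isoleucine replicate 1 (0.515), leucine replicate 1 (0.600), phenylalanine replicate 2 (0.261) and threonine replicate 2 (0.172). For one-carbon genes it held for asparagine replicate 1 (0.0563), asparagine replicate 2 (0.338), citrulline replicate 2 (0.131), isoleucine replicate 1 (0.312), leucine replicate 1 (0.132), threonine replicate 1 (0.0602), tryptophan replicate 1 (0.219) and tyrosine replicate 2 (0.388).

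Cytosolic ribosomal protein genes fell on 5 sources, namely glutamate, glutamine, phenylalanine, proline and serine, with medians of -0.39 to -0.30. On proline 1 of 130 rose and 57 fell (1 and 70 adjusted over the list alone, adjusted p = 0.00974), and on glutamate 1 of 126 rose and 48 fell (1 and 67 adjusted over the list alone, adjusted p = 0.00855). Every one of these 5 calls ended when an own array was left out, for glutamate replicate 2 (0.205), glutamine replicate 1 (0.250), phenylalanine replicate 1 (0.485), proline replicate 1 (0.299), serine replicate 1 (0.0555) and serine replicate 2 (0.352), the adjusted p in parentheses. Ribosome biogenesis genes fell on glutamate and phenylalanine and rose on asparagine, where the call ended with the replicate block (adjusted p = 0.0844). On phenylalanine 14 of 25 fell (19 adjusted over the list alone, adjusted p = 0.00264), and on asparagine 6 of 26 rose and 1 fell (6 and 1 adjusted over the list alone, adjusted p = 0.0434). NOP56, a nucleolar gene, was at 0.77 ± 0.13 on asparagine. Those calls ended for asparagine replicate 2 (0.693), glutamate replicate 1 (0.107), glutamate replicate 2 (0.0968) and phenylalanine replicate 1 (0.118).

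In energy metabolism, the retrograde and citric acid cycle list rose on leucine, methionine, phenylalanine, threonine and tyrosine and fell on glutamate and proline. On phenylalanine 8 of 17 rose (8 adjusted over the list alone, with 1 lower, adjusted p = 0.00264), led by the succinate dehydrogenase gene SDH2 (1.33 ± 0.20). Respiratory chain and ATP synthase genes rose on leucine, ornithine, phenylalanine, threonine and tyrosine. On ornithine 12 of 23 rose (15 adjusted over the list alone, adjusted p = 0.00252), with RIP1, an iron-sulfur protein gene, at 0.90 ± 0.14. Glycolysis and fermentation genes rose on ammonium, aspartate, glutamine, phenylalanine, proline, serine and valine. On aspartate 9 of 18 rose (12 adjusted over the list alone, adjusted p = 0.000145), and PGK1, a phosphoglycerate kinase gene, was at 1.73 ± 0.23. Stress and reserve carbohydrate genes rose on aspartate and phenylalanine and fell on isoleucine, where the call ended with the replicate block (adjusted p = 0.0594). On phenylalanine 4 of 12 rose (6 adjusted over the list alone, adjusted p = 0.0111), with CTT1 at 2.68 ± 0.44. Leaving out an own array ended the retrograde call with glutamate replicate 1 (0.0857), leucine replicate 1 (0.372), methionine replicate 1 (0.227), phenylalanine replicate 1 (0.0883), threonine replicate 1 (0.0799) and tyrosine replicate 1 (0.273). It ended the respiratory call with leucine replicate 1 (0.103), phenylalanine replicate 2 (0.0666), threonine replicate 2 (0.0582) and tyrosine replicate 1 (0.832). It ended the glycolysis call with ammonium replicate 2 (0.438), glutamine replicate 2 (0.390), phenylalanine replicate 1 (0.227), proline replicate 1 (0.152) and serine replicate 2 (0.306), and the stress call with aspartate replicate 2 (0.187), isoleucine replicate 1 (0.0830), isoleucine replicate 2 (0.281) and phenylalanine replicate 1 (0.289).

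Among nutrient lists, iron regulon genes rose on aspartate, isoleucine, ornithine, phenylalanine, serine, threonine, tyrosine and valine and fell on GABA. On threonine 7 of 9 rose (7 adjusted over the list alone, adjusted p = 1.5e-07), led by the siderophore transporter genes ARN1 (1.65 ± 0.14) and SIT1 (1.57 ± 0.14). Phosphate regulon genes rose on citrulline, tyrosine and valine and fell on alanine, asparagine, glutamate and ornithine. On alanine 1 of 8 rose and 4 fell (1 and 4 adjusted over the list alone, adjusted p = 0.000352), with PHO81, a regulator gene, at -0.64 ± 0.10. Ergosterol biosynthesis genes fell on GABA, alanine, arginine, asparagine, aspartate, methionine, serine and valine, the aspartate call ending with the replicate block (adjusted p = 0.0609). On alanine 8 of 12 fell (9 adjusted over the list alone, adjusted p = 2.0e-05), with the sterol desaturase gene ERG5 at -1.12 ± 0.15. The tested members of the thiamine and pyridoxine list fell on GABA, ammonium, asparagine, serine and threonine, though 6 of the 19 listed genes could be tested. The pyridoxine synthesis genes SNZ1 and SNO1 were not among them. On threonine they averaged 3.76 and 3.11 over 2 arrays, above urea and with no test. On serine 2 of 3 fell (2 adjusted over the list alone, adjusted p = 7.2e-05). Leaving out an own array ended the iron call with aspartate replicate 2 (0.198), isoleucine replicate 2 (0.439), ornithine replicate 2 (0.173) and phenylalanine replicate 1 (0.149). The phosphate call ended with alanine replicate 2 (0.101), asparagine replicate 2 (0.144), citrulline replicate 2 (0.211), glutamate replicate 1 (0.268), glutamate replicate 2 (0.0693), ornithine replicate 1 (0.187), ornithine replicate 2 (0.0683), tyrosine replicate 1 (0.0599), tyrosine replicate 2 (0.0850), valine replicate 1 (0.183) and valine replicate 2 (0.0747). The ergosterol call ended with GABA replicate 2 (0.105), arginine replicate 1 (0.978), asparagine replicate 2 (0.0670), aspartate replicate 1 (0.130), aspartate replicate 2 (0.258), methionine replicate 2 (0.754), serine replicate 1 (0.0829), serine replicate 2 (0.0647) and valine replicate 1 (0.260). The thiamine call ended with GABA replicate 1 (0.0700), GABA replicate 2 (0.0570), ammonium replicate 2 (0.730), serine replicate 1 (0.346) and threonine replicate 1 (0.930).

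**Figure D3:**
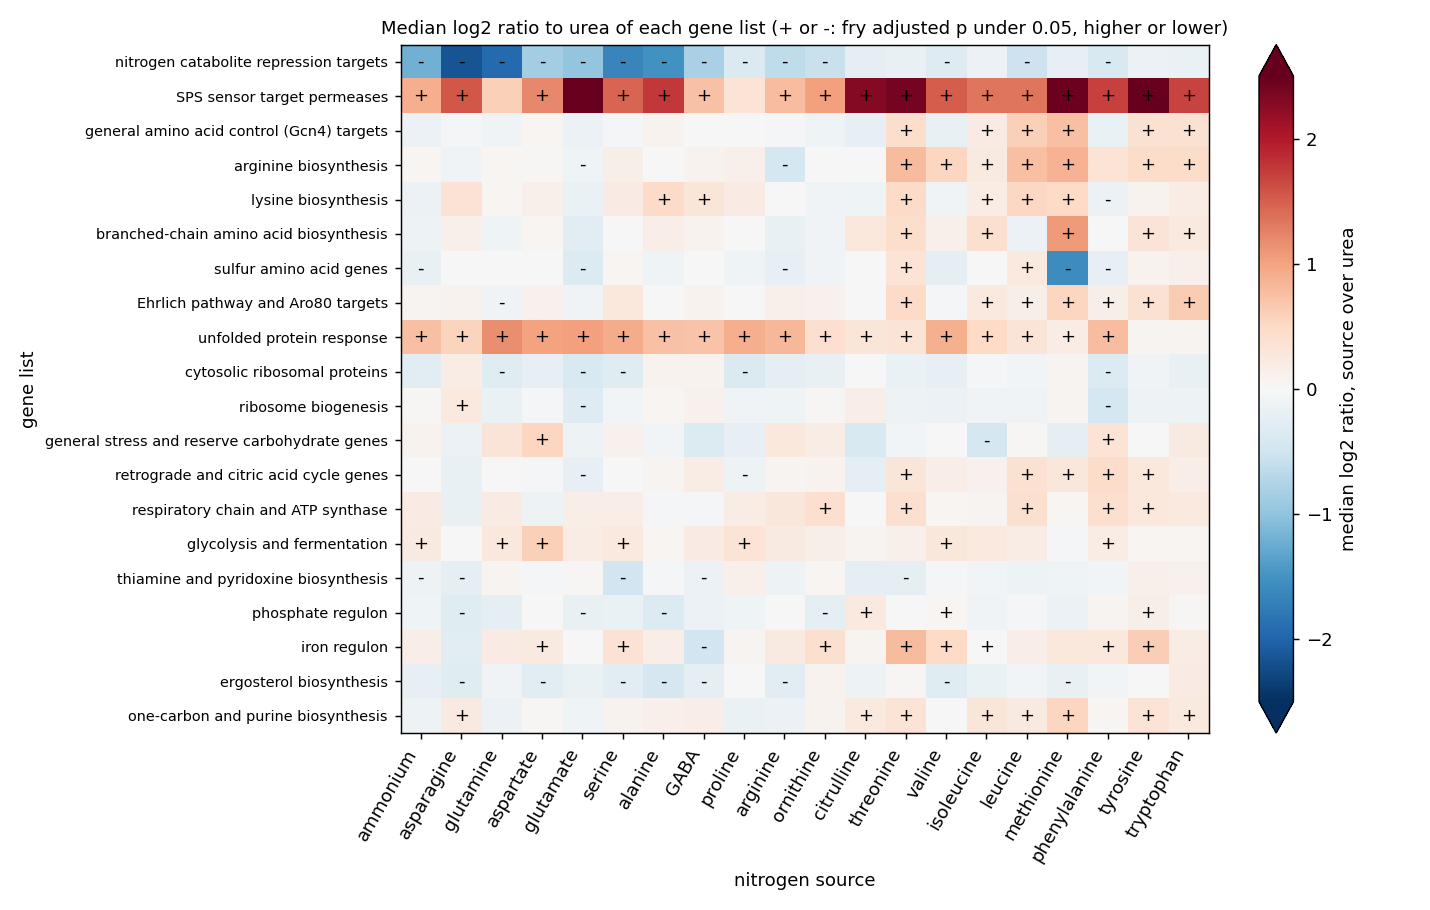
Median log2 ratio of source over urea for each of the 20 gene lists on each of the 20 nitrogen sources, on a colour scale that ends at ±2.5. A plus or a minus marks the 158 of 400 list tests that passed with fry, and the nitrogen catabolite repression list is marked as lower on 14 sources.

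Amino acids that leave fusel alcohols when their nitrogen is taken (leucine, isoleucine, valine, methionine, phenylalanine, tyrosine, tryptophan) were compared with the 13 other sources, the source being the unit. ARO10 was higher on average over the 7 fusel sources by 3.27 ± 0.86 (limma, adjusted p = 0.0492). It averaged 3.53 (SD 2.74, n = 7) there and 0.26 (SD 0.23, n = 8) elsewhere. Against urea ARO10 passed as higher on 5 of the 20 sources, so not on each of the 7. AGP1 was higher by 2.39 ± 0.64, DIP5 by 1.67 ± 0.35, the carbon-sulfur lyase gene IRC7 by 1.65 ± 0.40 and VBA1 by 1.57 ± 0.36. DIP5 averaged 0.30 (SD 0.55, n = 7) on the fusel sources and -1.36 (SD 0.92, n = 13) on the others. ESBP6 (1.55 ± 0.33), the serine dehydratase-like gene SDL1 (1.47 ± 0.33), YNR068C (1.27 ± 0.26) and RTC2 (1.15 ± 0.27) were also higher. CIS1 and YIL168W were higher too, but their calls ended without threonine replicate 1 (1.40 and 1.23). That of CIS1 also ended without isoleucine replicate 2 (1.31). CRN1, the coronin gene, was lower (-0.39 ± 0.09), and MYG1 (-0.38 ± 0.07), GCD10 (-0.37 ± 0.07), a tRNA methyltransferase subunit gene, and GET3 (-0.32 ± 0.07) were lower. The Ehrlich list averaged 0.89 (SD 0.82, n = 7) against -0.04 (SD 0.14, n = 13), with an exact permutation adjusted p of 0.00851, and 1 of 6 members was higher (3 adjusted over the list alone).

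Of 4082 genes, 119 differed between the classes with limma, 92 higher and 27 lower on the fusel sources. Arginine biosynthesis genes averaged 0.53 against 0.02 (SD 0.30 and 0.28, exact adjusted p = 0.0137, 1 of 7 higher, 5 adjusted over the list alone). Retrograde and citric acid cycle genes averaged 0.27 against -0.07 (SD 0.10 and 0.24, exact adjusted p = 0.0169, 2 of 17 higher, 10 adjusted over the list alone). SPS sensor permeases averaged 2.01 against 1.06 (SD 0.50 and 0.67, exact adjusted p = 0.0199, 2 of 6 higher, 2 adjusted over the list alone), and Gcn4 targets 0.36 against -0.02 (SD 0.36 and 0.18, exact adjusted p = 0.0199, 5 of 27 higher, 15 adjusted over the list alone). One-carbon and purine genes averaged 0.24 against 0.01 (SD 0.16 and 0.18, exact adjusted p = 0.0362, 2 of 11 higher, 2 adjusted over the list alone). The unfolded protein response list averaged 0.43 against 0.73 (exact adjusted p = 0.0596) and the catabolite repression list -0.45 against -1.14 (exact adjusted p = 0.0621, 1 of 27 higher, 12 adjusted over the list alone), and neither passed, nor did the other 12 lists. The smallest p that these 77520 exact permutations can give lies far below these values. Leaving out tryptophan and tyrosine left 2 of the 119 genes past the threshold, and none of the genes named here. The call of ARO10 ended when any of 14 arrays was left out in turn (differences 3.17 to 3.49), that of AGP1 with any of 13 (2.21 to 2.44) and that of IRC7 without threonine replicate 1 (1.61), where the whole count was 68.

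Pairs of related molecules, each at 10 mM, were compared next. The amides glutamine and asparagine differ from glutamate and aspartate by an amide in place of the side-chain acid. GAP1, the general amino acid permease gene, was lower on glutamine than glutamate (-3.43 ± 0.54) (n = 2 arrays per source) and lower on asparagine than aspartate (-3.80 ± 0.54). MEP2 was lower in both pairs (-3.03 ± 0.36 and -2.99 ± 0.36), and DAL80 was lower on asparagine (-3.63 ± 0.39). CIT2 was higher on glutamine by 2.05 ± 0.29. Of the catabolite repression list, 9 of 24 were lower (14 adjusted over the list alone; 5 without glutamate replicate 2 and 5 without glutamine replicate 2) on glutamine and 11 of 26 were lower (21 adjusted over the list alone; 3 without asparagine replicate 2, 3 without aspartate replicate 1 and 4 without aspartate replicate 2) on asparagine. DAL4 did not differ past the threshold in either pair, at -0.76 (95% interval -1.69 to 0.18) and -0.52 (95% interval -1.46 to 0.42). Between glutamine and glutamate 21 of 2871 tested genes differed, 5 higher and 16 lower (13 without glutamate replicate 1, 11 without glutamate replicate 2 and 9 without glutamine replicate 2). Between asparagine and aspartate 26 of 3702 tested genes differed, 1 higher and 25 lower (11 without asparagine replicate 2, 7 without aspartate replicate 1 and 6 without aspartate replicate 2).

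Leucine and isoleucine, isomers that differ in the position of a methyl group, were compared as leucine minus isoleucine. LEU2, a leucine synthesis gene, was lower (-2.00 ± 0.20) on leucine (n = 2 arrays per source), OAC1, a mitochondrial carrier gene for the leucine precursor, (-1.72 ± 0.19), and GDH2 (-1.92 ± 0.31), while the flocculin gene FLO11 was higher by 3.11 ± 0.46. Of the branched-chain synthesis list 3 of 10 were lower (4 adjusted over the list alone), and of Gcn4 targets 4 of 26 were higher (16 adjusted over the list alone; 1 without isoleucine replicate 2 and 1 without leucine replicate 1). In this pair 35 of 2953 tested genes differed, 20 higher and 15 lower (16 without isoleucine replicate 2, 16 without leucine replicate 1 and 19 without leucine replicate 2). VEL1 differed by 0.07 (95% interval -1.35 to 1.50) and DAL4 by 0.12 (95% interval -0.82 to 1.06), without passing. Isoleucine, with a methyl group more than valine in its side chain, gave higher CAR1 (1.84 ± 0.32), GDH2 (1.73 ± 0.31) and YNR068C (1.52 ± 0.24). These calls ended without isoleucine replicate 1 (1.52, 1.25 and 1.28), CAR1 also without valine replicate 1 (1.81) or 2 (1.86), and GDH2 without valine replicate 2 (1.64). Here 8 of 3014 tested genes differed, each higher on isoleucine (14 without isoleucine replicate 2 and 1 without valine replicate 2), and GAP1 differed by 0.39 (95% interval -0.72 to 1.49), not past the threshold.

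Phenylalanine lacks the hydroxyl group of tyrosine, and threonine has a methyl group that serine lacks. ARO10 was lower on phenylalanine than on tyrosine (-3.46 ± 0.56) (n = 2 arrays per source), a call that ended without phenylalanine replicate 1 (-2.97, adjusted p = 0.0774), and YOR062C was lower (-1.84 ± 0.25). Of Gcn4 targets, 10 of 26 were lower (16 adjusted over the list alone; 0 without phenylalanine replicate 1 with limma, where 13 were at an unadjusted p under 0.05, 3 without phenylalanine replicate 2 and 1 without tyrosine replicate 2) on phenylalanine. On phenylalanine against tyrosine 70 of 3253 tested genes differed, 21 higher and 49 lower (8 without phenylalanine replicate 1, 17 without phenylalanine replicate 2, 209 without tyrosine replicate 1 and 14 without tyrosine replicate 2). GAP1 differed there by -0.05 (95% interval -1.16 to 1.07), not past the threshold. CAR1 was lower on phenylalanine (-1.87 ± 0.33) and INO1 higher (1.90 ± 0.41). Neither call held without phenylalanine replicate 1 (-1.53 and 1.83) or tyrosine replicate 2 (-1.67 and 1.80). The calls of RAD27 and EEB1, both higher, ended without the same arrays. On threonine, DAL5 was higher than on serine by 3.53 ± 0.52, GAP1 by 3.18 ± 0.54 and DAL80 by 2.50 ± 0.39, and EUG1, a protein disulfide isomerase gene, was lower (-0.93 ± 0.15). AGP1 was higher by 3.28 ± 0.65, but not without serine replicate 1 (3.12) or threonine replicate 1 (2.44). HXT2 was lower (-0.96 ± 0.25), a call that ended without serine replicate 1 (-1.09), serine replicate 2 (-0.84) or threonine replicate 2 (-0.74). Of the catabolite repression list 18 of 24 were higher (21 adjusted over the list alone, with 1 lower). Between threonine and serine 102 of 2972 tested genes differed, 90 higher and 12 lower (55 without serine replicate 1, 52 without serine replicate 2 and 45 without threonine replicate 2), and CHA1 differed by 0.23 (95% interval -0.70 to 1.16), not past the threshold.

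Arginine carries a guanidino group and citrulline a ureido group where ornithine has an amine. Citrulline gave higher CAR1 (3.75 ± 0.32, n = 2 arrays per source), CAR2 (2.85 ± 0.24) and DAL4 (2.46 ± 0.46) than ornithine, and higher AGP1 (3.66 ± 0.65), a call that ended without ornithine replicate 2 (3.20). CTT1 was lower (-3.14 ± 0.62), though not without ornithine replicate 2 (-2.80). Of the catabolite repression list 7 of 24 were higher (8 adjusted over the list alone; 3 without citrulline replicate 2 and 3 without ornithine replicate 2). Between citrulline and ornithine 186 of 3075 tested genes differed, 106 higher and 80 lower (52 without citrulline replicate 2, 89 without ornithine replicate 1 and 43 without ornithine replicate 2). Between arginine and ornithine, ERP2, a vesicle trafficking gene, was higher by 0.98 ± 0.16 and RPL42A, a ribosomal protein gene, and SYT1 were lower (-1.20 ± 0.21 and -0.94 ± 0.14). Here 3 of 3117 tested genes differed, 1 higher and 2 lower with limma (1 without arginine replicate 1, 25 without arginine replicate 2, 7 without ornithine replicate 1 and 0 without ornithine replicate 2), against 275 at an unadjusted p under 0.05, and the 3 calls ended without arginine replicate 1 (0.95, -0.63 and -0.82) or ornithine replicate 2 (0.94, -1.28 and -0.73), and RPL42A also without ornithine replicate 1 (-1.13). CAR1 differed by -0.15 (95% interval -0.82 to 0.51) and GAP1 by -0.94 (95% interval -2.04 to 0.16), neither past the threshold.

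GABA is glutamate without its alpha-carboxyl group. UGA4 was higher on GABA by 4.52 ± 0.25 (n = 2 arrays per source), UGA2 by 4.13 ± 0.19, UGA1 by 3.91 ± 0.25 and GDH2 by 2.66 ± 0.31, and the siderophore transporter gene SIT1 was lower (-1.48 ± 0.19). Of ribosomal protein genes 8 of 123 were higher (55 adjusted over the list alone, with 1 lower; 0 without GABA replicate 1 with limma, where 21 were at an unadjusted p under 0.05, 0 without GABA replicate 2 with limma, where 70 were at an unadjusted p under 0.05 and 1 without glutamate replicate 2), and of the retrograde list 6 of 17 were higher (6 adjusted over the list alone, with 1 lower; 2 without GABA replicate 1 and 3 without glutamate replicate 1). In this pair 41 of 3443 tested genes differed, 31 higher and 10 lower (15 without GABA replicate 1, 17 without GABA replicate 2 and 20 without glutamate replicate 2). DAL5 differed by -0.28 (95% interval -1.35 to 0.78) and DAL4 by 0.86 (95% interval -0.07 to 1.80), not past the threshold. Counts in parentheses for a pair, or for a list in a pair, are those that moved by more than 1.5 times when the array named was left out.

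Genes with a textbook direction on their own source were read as a check of sign. UGA1, UGA2 and UGA4 on GABA, CAR1 and CAR2 on arginine, CHA1 on serine and threonine, PUT1 and PUT2 on proline, and ARO9 and ARO10 on the aromatic amino acids all lay above urea, and DUR3 on glutamine (-1.99 ± 0.31), ammonium (-2.25 ± 0.31) and asparagine (-2.62 ± 0.31), and GAP1, DAL5 and MEP2 on glutamine, below it. GAP1 was at -3.65 ± 0.38 on glutamine (SE, n = 2 arrays). In all, 42 of 42 arrays with a value pointed in the textbook direction over 21 of the 24 checks, and 17 of the 18 that could be tested passed, PUT1 on proline being the exception. ARO9, an aromatic transaminase gene, had values on fewer than 30 arrays and was not tested, and DUR1,2 was not analysed here.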

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

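The dye test of shared genes, the simulation of a shared urea error and the random lists set against the zinc list were chosen after the result was seen, and the patterns behind the ribosomal and class tests were known when those tests were set, though not the test results. LEU2, a leucine synthesis gene, and OAC1 moved in opposite directions on leucine and isoleucine. LEU2 differed by -2.00 ± 0.20 (-1.52 ± 0.14 on leucine, 0.48 ± 0.14 on isoleucine), and OAC1 by -1.72 ± 0.19 (-1.09 ± 0.13 on leucine, 0.63 ± 0.13 on isoleucine) (SE, n = 2 arrays per source, limma). DLD3 differed by 1.57 ± 0.17 (0.43 ± 0.12 on glutamine, -1.14 ± 0.12 on glutamate), and SAM3, an S-adenosylmethionine permease gene, by 1.49 ± 0.28 (0.64 ± 0.20 on glutamine, -0.84 ± 0.20 on glutamate). RPL7B differed by 1.01 ± 0.21 (0.49 ± 0.15 on asparagine, -0.52 ± 0.15 on aspartate). ERP2 differed by 0.98 ± 0.16 (0.65 ± 0.11 on arginine, -0.33 ± 0.11 on ornithine) and SYT1 by -0.94 ± 0.14 (-0.32 ± 0.10 on arginine, 0.62 ± 0.10 on ornithine). INO1 differed by -2.10 ± 0.40 (-1.16 ± 0.28 on citrulline, 0.94 ± 0.28 on ornithine). Each of these stood out because the gene passed in opposite directions on both members of a pair and in the difference itself. When single arrays were left out the calls ended for SAM3 without any of the 4 arrays of its pair (1.38 to 1.59) and RPL7B in the same way (0.99 to 1.03). ERP2 and SYT1 lost theirs without arginine replicate 1 (0.95 and -0.82) or ornithine replicate 2 (0.94 and -0.73). INO1 lost it without citrulline replicate 2 (-1.87) or ornithine replicate 2 (-1.85).

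Genes of the fixed lists with values on fewer than 30 arrays were not tested. Of these 54, 7 had both arrays of a source over 2 in size and in the same direction. ARO9, an aromatic transaminase gene, averaged 5.07 on tyrosine. SNZ1 and SNO1, pyridoxine synthesis genes, averaged 4.45 and 3.95 on methionine, and the permease gene BAP3 4.19. ALD3, an aldehyde dehydrogenase gene, averaged 2.81 on phenylalanine. The phosphate genes PHO84 and SPL2 averaged 2.81 and 2.69 on tyrosine. These are means of 2 arrays with no test.

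Of the tested genes, 108 changed the same way on at least 15 of the 20 sources, 62 higher and 46 lower. A dye bias in one of the 2 array tables would put the shift in a single table, but the median ratio of the smaller to the larger table mean was 0.755, and all 108 had the same sign in both, with 9 at a ratio under 0.5, ZPS1 and PST1 of the zinc-responsive list among them. In 20 simulated data sets, an error of the urea RNA shared by all arrays, as large as the residual spread, gave 31.4 such genes on average and 42 at most, so part of the 108 may come from such an error, if the arrays shared 1 urea RNA, which the labels do not say. A zinc supply differing between urea and the other cultures is a candidate explanation for some, since a zinc-responsive list was higher on 20 sources. All sources are set against urea, however, and 7 of 100 random lists of 12 tested genes were higher on at least 15 sources, the highest on 19. The random lists were drawn from all tested genes, and VEL1, IZH1, ZRC1 and ADH4 each sat in a list among these 7. That background is thus not free of the zinc-responsive genes themselves. Dye bias of opposite sign in the 2 tables and an effect of growth on urea itself stay open.

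The cytosolic ribosomal protein list was lower on 5 sources, and every one of these calls ended when an own array was left out, with adjusted p values given in the results. An intensity-dependent dye bias of abundant transcripts would pull the medians of the opposite arrays of a source apart. Both medians were below 0 on the 5 sources. These were picked for a low fit over the same arrays, so that result cannot decide about such a bias. The 2 medians were -0.52 and -0.15 on phenylalanine and -0.38 and -0.21 on glutamine, and 0.05 and -0.49 on arginine, which was not called. Cross-hybridisation between paralogous copies would spare single-copy genes. Their median was below 0 on the 5 sources (-0.57 on proline to -0.29 on glutamine), so the fall was not in genes with a paralogous copy alone. The 5 sources were picked for a low list that holds these genes. The single-copy median was also below 0 on alanine (-0.12), where that of the list was above 0 (0.10). Its sign alone thus cannot decide about cross-hybridisation. A dye bias of opposite sign in the 2 tables would shift every source alike, so alone it cannot give the gap between glutamate (array medians of -0.23 and -0.54) and asparagine (0.21 and 0.14), though a part of the fall shared by all sources stays open. A lower growth rate was not tested, since growth rates are not given in the sources used here.

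The fusel class comparison gave 119 genes, and 1 of 100 splits of the 20 sources into 7 and 13, the real one, gave as many. The highest other split gave 90 genes and held 5 fusel sources with threonine and aspartate. No other split drawn gave 119 genes with all arrays, which makes an arbitrary division of the sources less likely as a cause but does not exclude it. The count was 68 without threonine replicate 1 and 85 without tyrosine replicate 1, both below 90. It was 434 with threonine in the fusel class, and no other splits were run in these settings. One dye orientation of tryptophan and tyrosine would shrink the differences without them, but the median ratio of the differences without to with both was 0.894, though 2 genes were then past the threshold. The Ehrlich pathway difference between the classes stays among the open explanations, since it was not tested apart from the other properties the 7 amino acids share.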

How the results depend on the processing

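Alternatives to the processing were set before the data were examined, except the filter of at least 20 arrays, which was chosen after the data had been seen. Subtracting array medians, the median of spots, the filter of at least 20 arrays and the replicate block in place of the dye term each left all 32 counts within 1.5 times. All but the filter could change little. Array medians were near 0 as deposited. Most genes had 2 spots (5395 of 5411 and 5538 of 5557), whose median is their mean. The block equals the dye term except on replicate 1 of tryptophan and tyrosine. The value of no named gene changed sign under any of the alternatives, apart from CAR2 on ornithine. CAR2 was not past the threshold there (-0.26 without ornithine replicate 1, 0.39 without ornithine replicate 2). Named genes fell short of the threshold in 9 of 268 cases with no dye term, 3 with the block, 4 with array weights, 2 with at least 20 arrays, 45 of 244 with the arrays of the comparison alone and 150 of 1546 when an array was left out. With genes on all 40 arrays 0 of 177 did. With the arrays of the comparison alone PUT1 on proline passed. The block calls lost were those of SEC63 in the class comparison, HPF1 in citrulline minus ornithine and WSC4 in GABA minus glutamate. The number of arrays, 2 per source, limits precision, and signal over background is not given in the sources used here.

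With no dye term, counts became 479 on GABA, 511 on alanine, 506 on ammonium, 318 on arginine, 586 on asparagine, 478 on aspartate, 179 on citrulline, 427 on glutamate, 517 on glutamine, 127 on isoleucine, 395 on leucine, 586 on methionine, 368 on ornithine, 452 on phenylalanine, 342 on proline, 469 on serine, 441 on threonine, 295 on tryptophan, 273 on tyrosine, 344 on valine, 13 for glutamine minus glutamate, 10 for asparagine minus aspartate, 10 for leucine minus isoleucine, 4 for isoleucine minus valine, 26 for phenylalanine minus tyrosine, 61 for threonine minus serine, 47 for citrulline minus ornithine and 18 for GABA minus glutamate. On tryptophan and tyrosine the dye term also changes the fitted values. On the 18 other sources these are the same without it. There the larger spread, in which the dye effect is left, lowered the counts. With array weights they became 305 on arginine, 1525 on asparagine, 1592 on aspartate, 146 on citrulline, 1237 on glutamine, 101 on isoleucine, 1207 on serine, 221 on tryptophan, 146 on tyrosine, 35 for glutamine minus glutamate, 211 for asparagine minus aspartate, 12 for leucine minus isoleucine, 5 for isoleucine minus valine, 25 for phenylalanine minus tyrosine, 165 for threonine minus serine, 122 for citrulline minus ornithine and 75 for GABA minus glutamate. Both arrays of a source had the same weight, from 0.54 on tryptophan to 1.80 on aspartate, so the weights act as a spread per source. Among the sources named, counts rose where the weight was high and fell where it was low. The spread shared by all arrays in the main fit may thus not hold for every source. Why the spread differed between sources was not tested. With genes on all 40 arrays fewer genes were tested, and counts became 317 on GABA, 329 on alanine, 335 on ammonium, 282 on arginine, 392 on asparagine, 351 on aspartate, 156 on citrulline, 319 on glutamate, 342 on glutamine, 143 on isoleucine, 280 on leucine, 335 on methionine, 315 on ornithine, 299 on phenylalanine, 285 on proline, 358 on serine, 335 on threonine, 269 on tryptophan, 191 on tyrosine, 276 on valine, 17 for asparagine minus aspartate, 12 for leucine minus isoleucine, 33 for phenylalanine minus tyrosine, 1 for arginine minus ornithine, 105 for citrulline minus ornithine, 917 in the F-test and 58 for the class comparison. With only the arrays of the comparison, which leaves fewer arrays to estimate the spread, counts became 282 on GABA, 176 on alanine, 237 on ammonium, 3 on arginine, 18 on citrulline, 131 on glutamate, 485 on glutamine, 12 on isoleucine, 112 on leucine, 371 on methionine, 145 on ornithine, 370 on phenylalanine, 260 on proline, 487 on serine, 543 on threonine, 65 on tryptophan, 215 on tyrosine, 133 on valine, 3 for glutamine minus glutamate, 1 for asparagine minus aspartate, 0 for leucine minus isoleucine, 0 for isoleucine minus valine, 3 for phenylalanine minus tyrosine, 62 for threonine minus serine, 0 for arginine minus ornithine, 2 for citrulline minus ornithine and 10 for GABA minus glutamate. Where limma gave 0 there, the counts at an unadjusted p under 0.05 were 116, 128 and 84, in the order given.

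The class comparison gave 434 genes with threonine in the fusel class, sharing 117 of the 119. It gave 987 with arrays as the unit, which counts arrays in place of sources. Without tryptophan and tyrosine it gave 2, both shared, with 5 fusel sources left and 660 genes at an unadjusted p under 0.05, and the calls of all 24 named class genes ended.

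Leaving out an array leaves its source with a lone array, assumed to vary like the others. Counts then ranged from 213 to 441 on GABA, 379 to 382 on alanine, 262 to 413 on ammonium, 316 to 339 on arginine, 318 to 533 on asparagine, 229 to 354 on aspartate, 129 to 241 on citrulline, 218 to 344 on glutamate, 292 to 345 on glutamine, 136 to 150 on isoleucine, 248 to 287 on leucine, 366 to 499 on methionine, 250 to 260 on ornithine, 181 to 305 on phenylalanine, 226 to 251 on proline, 296 to 321 on serine, 229 to 355 on threonine, 268 to 528 on tryptophan, 240 to 361 on tyrosine, 140 to 237 on valine, 9 to 15 for glutamine minus glutamate, 6 to 24 for asparagine minus aspartate, 16 to 39 for leucine minus isoleucine, 1 to 14 for isoleucine minus valine, 8 to 209 for phenylalanine minus tyrosine, 45 to 79 for threonine minus serine, 0 to 25 for arginine minus ornithine, 43 to 136 for citrulline minus ornithine, 15 to 38 for GABA minus glutamate and 68 to 160 for the class comparison. The F-test gave 2607 to 2818 genes and the list tests 148 to 166 calls. The 0 of arginine minus ornithine was without ornithine replicate 2, with limma and 285 genes at an unadjusted p under 0.05. Arrays that moved a count by more than 1.5 times are named beside that count in the results.

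With no dye term 143 of the 158 list calls were kept, 15 were lost and 4 were gained. With the block 152 of the 158 list calls were kept, 6 were lost and 5 were gained, and with array weights 149 of the 158 list calls were kept, 9 were lost and 18 were gained. With genes on all 40 arrays, 103 were kept, 48 lost and 7 reversed, and 29 were gained. The reversed calls were those of the SPS list on GABA (adjusted p = 0.0275), ammonium (adjusted p = 0.00266), arginine (adjusted p = 0.0211), asparagine (adjusted p = 0.00190), aspartate (adjusted p = 0.0234) and ornithine (adjusted p = 0.0177) and of the Ehrlich list on phenylalanine (adjusted p = 0.0108). There the SPS list holds DIP5 alone and the Ehrlich list ARO8 and BAT1, so the reversal follows from the members left.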

Other observations

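Several zinc-responsive genes were higher than on urea on most sources, in lists that were all written after the data had been seen. ZRC1, a vacuolar zinc transporter gene, was higher on 20 of 20 sources (mean 0.97), ZPS1 on 19 of 20 (mean 1.48, with 0.72 and 2.18 in the 2 tables), the regulator gene ZAP1 on 15 of 19 and IZH1 on 16 of 17. The plasma membrane zinc transporter genes ZRT1 and ZRT2 were higher on 7 of 20 and 3 of 19. The zinc-responsive list, without VEL1, YOR387C and ADH4, was higher on 20 sources, with medians of 0.29 to 1.02 over 12 tested genes. ADH4, an alcohol dehydrogenase gene that zinc shortage raises, was higher on 18 of 19 (mean 1.97), while ADH1 was lower on 4 of 20 and ADH3 on 9 of 19. All comparisons are with urea, so the 20 sources are not 20 separate observations of a difference from it. Of 100 random lists of 12 tested genes, 7 were higher on at least 15 sources, the highest on 19. These were drawn from all tested genes, and VEL1, IZH1, ZRC1 and ADH4 each sat in a list among the 7, ADH4 in the highest. Random lists with ZPS1 and ZRT1 were higher on 3 and 12 sources. A difference in zinc supply between urea and the other cultures stays a hypothesis, found and tested on the same data.

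Each of 4 further lists holds genes already noticed, so these are hypotheses picked from the data. By fry, the cell wall protein list was higher on 17 sources on balance, with 3 to 8 members past the threshold as higher and 0 to 1 as lower per source, led by SED1 (20 sources), TIP1 (19, mean 1.52) and PST1 (17), while CCW12, CCW14, HSP150 and PIR1 passed on 0. The glyoxylate and peroxisomal list was lower on 13, with 2 to 4 members past the threshold as lower and 0 to 1 as higher per source, carried by MLS1 (15 sources, mean -2.09) and FAA3 (13), while MDH3 was higher on 5, CIT2 was higher on 5 and lower on 3, and ECI1, ICL1 and CTA1 passed on 0. The hexose transporter list, of 4 tested genes, was lower on 12, with 1 to 2 members past the threshold as lower and 0 to 1 as higher per source, from HXT2 (15 sources, mean -1.03) and HXT3 (15, mean -0.66), while HXT1 was higher on 6. The autophagy list was lower on 11, with 1 to 8 members past the threshold as lower and 0 to 3 as higher per source, with ATG32 lower on 13 sources, ATG1 on 12, ATG31 on 8, ATG9 on 7, ATG4 on 6, ATG5 on 5 and ATG26 on 4, while ATG19 was higher on 5 and ATG17 and ATG3 on 4 each. Among ATG genes left out of the autophagy list, ATG41 was higher on 17 sources and lower on 0, and ATG23 was higher on 3. ATG42 and ATG45, also left out, were lower on 7 each. No explanation was tested for these 4 lists.

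Every array carries urea RNA, and the labels do not say whether it was the same RNA each time. The median correlation between sources across genes was 0.621, against 0.665 in simulations with a shared urea error and 0.00 with separate errors. The median covariance was 0.0904, against at most 0.0410 with the shared error. These values do not separate a shared error from a real shift against urea common to the sources. Genes are not independent replicates.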
